A study of Mus musculus with 6 samples.

How the data were processed

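RNA was measured in fetal livers of 6 mouse embryos at embryonic day 12.5, 3 Rb null and 3 wild type, from matings of Rb heterozygous 129sv mice. Livers were dissected and disaggregated in saline, total RNA was extracted with Trizol, and 6 ug were used to make biotin-labelled cRNA for one Affymetrix mouse array per embryo. Replicates are therefore separate embryos, and no batch, date or sex is given in the labels. Per the labels, the authors computed the deposited signal values with MAS5, whose version and scaling target are not stated. The deposited values are linear, neither centred nor log-transformed, and the 2% trimmed mean of each of the 6 arrays was about 500.2 signal units, so the arrays had been scaled to a common level.

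Probe sets were assigned to genes by the platform annotation, and symbols and gene order came from a RefSeq gene table of the mouse genome. Of the probe sets, 10833 had 1 gene symbol, 396 had several symbols and 1193 had none. Those with several symbols or none could be tested but stood for no gene. The other 66 were array controls, which were left out of the test and examined apart. An offset of 50.02 (0.1 of the trimmed mean) was added before taking log2, and probe sets with a mean signal over all arrays above 150.1 (0.3 of the trimmed mean) were tested. These were 6793 probe sets, counted whether or not they had a single symbol, and 5273 of the 8251 genes on the array were tested. Each gene was represented by its probe set with the highest mean signal. Rb null and wild type livers were compared with limma 3.58.1 in R 4.3.3 (moderated two-sided test with an intensity trend), with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. A gene was called higher or lower only past that threshold.

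Gene lists were written before the data were examined. They were 26 lists of 804 genes, of which 646 were on the array, for the E2F family, cell cycle, erythroid maturation, other cell types of the fetal liver, hypoxia, mitochondria, stress, tissue handling and sex. Lists with at least 3 tested genes, 23 in all, were tested with camera at a preset correlation of 0.01 against the other genes, and again with the correlation estimated from the arrays. The fry test, which asks whether the genes of a list move one way on balance and makes no comparison with other genes, served as an alternative. P values were adjusted over the 23 lists. The median of each list was also set against the 95% range of medians of 10000 random lists matched on mean signal. Counts of changed members are given after adjustment over all tested probe sets and adjusted over the list alone. The single values of array quality were compared by two-sided exact permutation tests, for which 3 against 3 allows no p below 0.1.

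Genes to be named were chosen by a rule written before the data were examined. It took the mutated gene and its E2F family, the 12 largest rises and the 12 largest falls past the threshold whose groups did not overlap, up to 4 members per list past the threshold with the largest change (or, where fewer than 2 passed, the 2 with the smallest p), and the globins. Genes named outside this rule are said to be so.

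Alternatives planned before the data were examined were quantile normalization, median scaling, offsets of 10.005 and 150.1, no filter and a stricter filter of 500.2. Also planned were no intensity trend, a robust trend, the replicate number as a block and the mean of a gene's probe sets. The others were leaving out probe sets with a suffix letter of s, f, r, g or i, a 2-fold minimum, an estimated correlation, fry, and leaving out each embryo in turn. Probe sets with these letters are called below shared-probe suffixes or probe sets that can bind several transcripts, although not each letter marks that. Cyclic loess normalization, the E2F list without Rb1 and the terminal erythroid list without the neighbours of Rb1 were added after seeing the data. The procedure was tested on simulated data of 3 against 3 arrays. There it recovered 23.1% of changes of 0.3, 79.7% of changes of 0.6 and 87.5% of changes of 1 on the log2 scale, with 5.76% false calls, and called the list that had been moved and no other list. The simulated probe sets varied independently of each other, and a smaller share of them was changed than in the real arrays. The simulation therefore does not show the error rate of the list tests, or the recovery, in the real data. Other splits of the 6 real arrays into 3 and 3 were fitted as the real comparison was.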

Results

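Transcript levels were measured in whole fetal livers of 6 mouse embryos at embryonic day 12.5. The embryos came from crosses between 129sv mice heterozygous for the retinoblastoma gene, and 3 were Rb null while 3 were wild type. The retinoblastoma protein restrains E2F transcription factors and thereby entry into the cell cycle, and embryos without it are known to die in mid-gestation with defects that include anaemia. At this age the liver is the main site of red cell production, and it also holds hepatoblasts, macrophages, megakaryocytes, endothelium and mesenchyme. The comparison asks which transcripts differ between Rb null and wild type livers. Each embryo was read on its own Affymetrix mouse array, so n = 3 embryos per genotype throughout. Levels are MAS5 signals given as mean ± SD, and log2 fold changes (Rb null minus wild type, on the scale of log2 of signal plus an offset of 50.02) are given ± SE. Folds are on that same scale, which understates the change of dim genes. The number of arrays limits the precision.

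The arrays had almost equal 2% trimmed means, between 500.22 and 500.25, whereas the median signal was 199 ± 2.97 in Rb null and 181 ± 5.22 in wild type arrays (exact permutation p = 0.1, the smallest that 3 against 3 allows). Across probe sets, which are not independent of each other, log2 values correlated with r between 0.982 and 0.988 within a genotype and between 0.966 and 0.973 across genotypes. The first principal component held 53.6% of the variance and separated the genotypes, from -12.8 to -9.81 in Rb null and from 10.4 to 12.7 in wild type arrays.

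Rb1 itself was the gene that fell most. Its signal was 136 ± 7.52 in Rb null and 750.1 ± 42.3 in wild type livers, so that Rb null livers had at most 18.1% of the wild type signal (log2 fold change -2.10 ± 0.09, limma adjusted p = 7.8e-06). Another Rb1 probe set read 89.1 ± 15.95 against 404 ± 25.5 (-1.71 ± 0.12). The Rb null means lay below the signal filter of 150.1 and were not shown to be above background. All 3 Rb null embryos lay below all 3 wild type embryos on each of the probe sets. Where these probes lie relative to the deleted part of the gene is not given in the sources used here, and a probe outside that part would not check the genotype labels.

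Of the other measured E2F family members and pocket proteins, Tfdp1, the dimerisation partner of E2F proteins, fell to 3593 ± 118 from 4775 ± 453 (-0.40 ± 0.07, adjusted p = 0.0068). E2f1 (-0.05 ± 0.08), E2f5 (0.08 ± 0.10), E2f8 (-0.14 ± 0.11) and the pocket protein gene Rbl1 (0.05 ± 0.07) did not pass the test, and E2f3 and Rbl2 stayed below the signal filter. The list therefore had 2 of 6 tested members lower, the same count adjusted over the list alone, with a camera adjusted p = 0.044 in the downward direction and an adjusted p = 0.15 with an estimated correlation. The list median of -0.10 lay within the 95% range of random lists matched on signal (-0.18 to 0.23). Without Rb1, an alternative added after seeing the data, the list no longer passed camera (adjusted p = 0.36), and leaving out Rb null embryo 3 (adjusted p = 0.057) or wild type embryo 1 (adjusted p = 0.061) also ended the call.

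Among 5273 tested genes, 690 (13.1%) were higher and 501 (9.50%) were lower in Rb null livers at a limma adjusted p below 0.05. Most changes were small. The median absolute log2 fold change of the 1191 changed genes was 0.38, and at least 2-fold changes numbered 27 upward and 3 downward. The 3 values of one genotype all lay beyond the 3 of the other for 1188 of the changed genes and for 41.2% of all tested genes, where chance gives 10%. Scaling the arrays to equal medians gave 497 higher and 836 lower genes, so that 37.3% of the calls were upward against 57.9% with the deposited scaling. Fewer genes were called without Rb null embryo 1 (427 higher, 290 lower), without Rb null embryo 2 (419 and 295) or without wild type embryo 3 (459 and 256).

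The gene with the largest rise was Ctse, which encodes the aspartic protease cathepsin E. Its brightest probe set rose 6.70-fold, from 519 ± 21.9 to 3761 ± 36.1 (2.74 ± 0.06, adjusted p = 1.1e-07), but another Ctse probe set fell from 998 ± 18.1 to 504 ± 54.7 (-0.92 ± 0.08). Ddit4, an inhibitor of mTOR signalling induced by stress, rose 5.25-fold from 150.4 ± 14.6 to 1002 ± 85.4 (2.39 ± 0.10, adjusted p = 7.8e-06). Igfbp1, a secreted binding protein of insulin-like growth factors, rose 4.05-fold to 3212 ± 230.0 (2.02 ± 0.07, adjusted p = 2.2e-06). Gas5, a non-coding host gene of small nucleolar RNAs, rose 3.34-fold to 2139 ± 42.7 (1.74 ± 0.06). The inducible chaperone genes Hspa1a (1.89 ± 0.16) and Hspa1b (1.53 ± 0.11) also rose. Completing the 12 largest rises were Bhlhe40, a transcriptional repressor (1.41 ± 0.11), Bnip3, a mitochondrial protein of cell death and mitophagy (1.35 ± 0.10), Stc2, a secreted glycoprotein (1.27 ± 0.11), Pea15a (1.26 ± 0.25), Grb10, an imprinted adaptor of insulin signalling (1.26 ± 0.07), and Pik3r2, a regulatory subunit of phosphoinositide kinase (1.22 ± 0.29, adjusted p = 0.021). In wild type livers the mean signals of Hspa1a, Hspa1b, Bhlhe40, Stc2 and Pea15a, between 62.4 and 113, lay below the filter of 150.1 and were not shown to be above background, so the sizes and ranks of these rises are uncertain. The Pik3r2 call was lost without Rb null embryo 1 (adjusted p = 0.077) or without Rb null embryo 2 (adjusted p = 0.073).

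After Rb1, the largest falls were those of Bpgm and Xpo7. Bpgm, which encodes the bisphosphoglycerate mutase of red cells, fell from 2403 ± 136 to 843 ± 62.9 (-1.46 ± 0.07, adjusted p = 2.3e-05). Xpo7, an exportin of maturing erythroblasts, fell from 5522 ± 269 to 2257 ± 107 (-1.27 ± 0.06, adjusted p = 1.8e-05). The metallothionein gene Mt1 fell from 9968 ± 485 to 5137 ± 338 (-0.95 ± 0.06), and Irgm2, an immunity-related GTPase, fell from 1532 ± 106 to 765 ± 55.5 (-0.96 ± 0.08). The remaining falls among the 12 were 1300017J02Rik (-0.89 ± 0.09), Sowaha (-0.89 ± 0.08), Ube2o, a ubiquitin-conjugating enzyme of reticulocytes (-0.86 ± 0.06), the phosphatase gene Ptp4a3 (-0.86 ± 0.07), Actb (-0.85 ± 0.22), the tetraspanin gene Cd82 (-0.80 ± 0.10) and the mitochondrial ribosomal protein gene Mrps25 (-0.77 ± 0.09). Without probe sets that can bind several transcripts the Mrps25 change shrank to -0.17 and the call was lost (adjusted p = 0.23). The Actb probe set was dim, at 230.1 ± 46.8 against 467 ± 159, while the 3 prime actin control of the array read 11920 ± 643 against 12834 ± 817 (-0.11 ± 0.07). Its call was lost on leaving out any embryo except wild type embryo 1, with adjusted p values from 0.051 to 0.070.

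**Figure D1:**
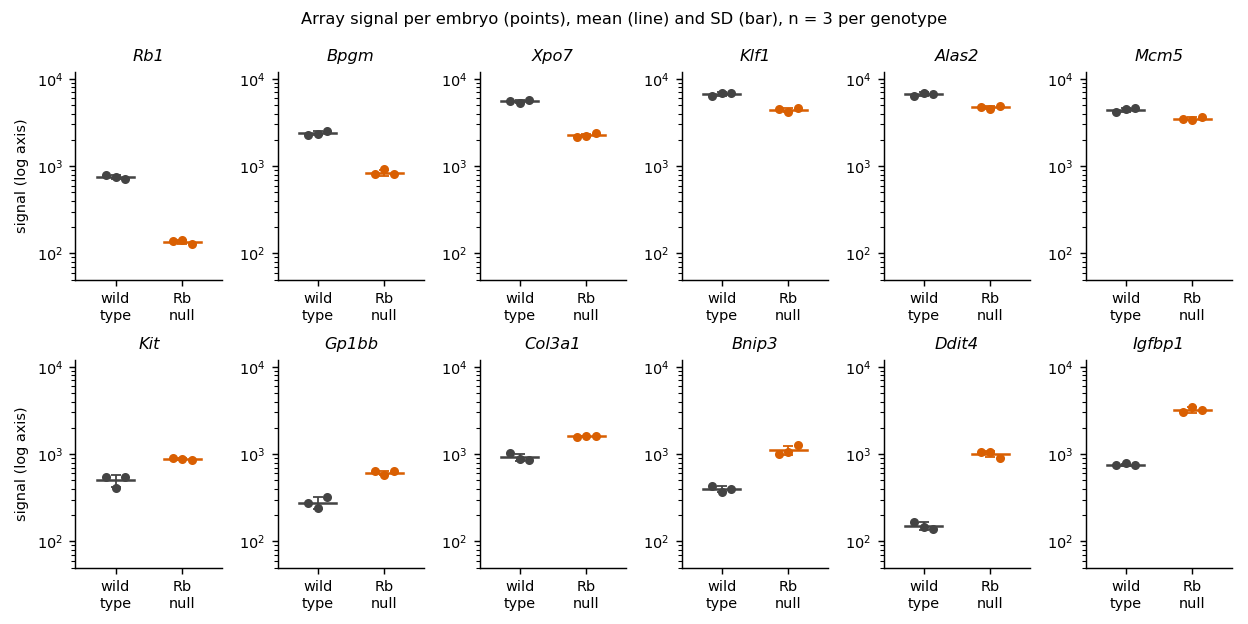
Array signal of 12 named genes in each embryo on a log axis, with points for embryos, lines for genotype means and bars for SD (n = 3 per genotype). The 3 Rb null embryos lie below the 3 wild type embryos for Rb1, Bpgm, Xpo7, Klf1, Alas2 and Mcm5 and above them for Kit, Gp1bb, Col3a1, Bnip3, Ddit4 and Igfbp1.

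Genes of the red cell membrane and of terminal erythroid maturation were lower in Rb null livers. Of 27 tested members, 16 fell, 2 rose and 9 did not pass the test, with the same counts adjusted over the list alone. The median log2 fold change was -0.31 (camera adjusted p = 6.4e-08, or adjusted p = 0.023 with an estimated correlation). After Bpgm, Xpo7 and Ube2o came Ank1, the ankyrin of the red cell membrane skeleton, from 7148 ± 675 to 4630 ± 238 (-0.62 ± 0.08), and Slc4a1, the anion exchanger of red cells, fell by 0.49 ± 0.06 on the log2 scale. The members that rose were Alox15, a lipoxygenase of late reticulocytes (0.90 ± 0.13, from a wild type mean of 136 that lay below the signal filter), and Aqp1, a water channel that endothelium also makes (0.61 ± 0.09, or 0.21 with adjusted p = 0.31 for the mean of its probe sets). Ank1, Slc4a1 and Aqp1 were picked for naming after their values were seen. The lists of mesenchyme, endothelial, megakaryocyte, granulocyte and macrophage genes described further on passed camera upward in the same livers, those of megakaryocytes and macrophages only at the preset correlation. Bright probe sets leaned lower in Rb null arrays, with a median log2 fold change of -0.15 in the brightest 10% of the genes and 0.09 in the dimmest 10%, and after cyclic loess normalization the median of this list was -0.16.

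Haem synthesis genes fell as well. Of 11 tested members 7 fell and 4 did not pass, the same count adjusted over the list alone (median -0.30, camera adjusted p = 1.6e-04, or adjusted p = 0.038 with an estimated correlation). Alas2, the erythroid enzyme of the first step of haem synthesis, fell from 6679 ± 306 to 4737 ± 209.8 (-0.49 ± 0.06, adjusted p = 0.0011). Alad (-0.41 ± 0.06), Tmem14c (-0.40 ± 0.06) and Urod (-0.38 ± 0.06) also fell.

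Of the adult-type globins, Hbb-b2 fell from 14729 ± 547 to 12357 ± 560.0 (-0.25 ± 0.06, adjusted p = 0.016) and Hba-a1 read 16316 ± 1370.4 against 19147 ± 1062 (-0.23 ± 0.07, adjusted p = 0.056). Both were past the threshold when adjusted over the list alone. The embryonic globins Hbb-y (-0.22 ± 0.07), Hbb-bh1 (-0.19 ± 0.07) and Hba-x (-0.16 ± 0.08) did not pass over all genes, whereas 2 of the 3 passed adjusted over the list alone (camera adjusted p = 0.063, or adjusted p = 0.25 with an estimated correlation). After median scaling, Hba-a1 (adjusted p = 0.029), Hbb-y (adjusted p = 0.025) and Hbb-bh1 (adjusted p = 0.024) passed over all genes. Hba-a1 also passed without Rb null embryo 3 (adjusted p = 0.035) or wild type embryo 1 (adjusted p = 0.049), and Hbb-y without wild type embryo 1 (adjusted p = 0.030). With the stricter filter Hba-a1 (adjusted p = 0.0488) and Hbb-y (adjusted p = 0.0478) passed as well. These globin values depended on the scaling. After quantile normalization Hbb-b2 read -0.03 (adjusted p = 0.52) and the embryonic globin median was 0.00, and after cyclic loess normalization they were -0.02 (adjusted p = 0.64) and 0.01. The globins are among the brightest probe sets. Quantile normalization gives equal ranks equal values, and cyclic loess is fitted there through few probe sets, so differences at the top shrink by construction. These losses therefore cannot decide whether the globin falls come from scaling. As deposited, the embryonic globin median of -0.19 lay within the range of random lists matched on signal (-0.38 to -0.15). Those random lists had a median of -0.23, so the embryonic globin median was no lower than that of equally bright genes. This comparison was not made for the adult-type globins. The Hbb-b2 call was also lost with no filter (adjusted p = 0.0544) and without Rb null embryo 1 (adjusted p = 0.0504), wild type embryo 2 (adjusted p = 0.054) or wild type embryo 3 (adjusted p = 0.065).

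Transcription factors of the erythroid lineage moved in both directions. Of 25 tested, 8 fell and 3 rose, or 11 and 6 adjusted over the list alone (median -0.15). The list passed camera in the downward direction (adjusted p = 0.012), with adjusted p = 0.076 with an estimated correlation. Klf1, a master regulator of red cell genes, fell from 6702 ± 282 to 4418 ± 226 (-0.60 ± 0.06, adjusted p = 4.9e-04), followed by Klf3 (-0.41 ± 0.07), Nfe2 (-0.39 ± 0.05) and Lyl1 (-0.35 ± 0.05). The Klf3 call was lost with the mean of its probe sets (-0.21, adjusted p = 0.056) and the Lyl1 call without probe sets that can bind several transcripts (-0.17, adjusted p = 0.085). Gata1, named after its value was seen, fell by 0.25 ± 0.06, but its call was lost on leaving out any embryo except Rb null embryo 1 (adjusted p values from 0.0504 to 0.074) and with the mean of its probe sets (-0.04, adjusted p = 0.79). The members that rose, Id1 (0.33 ± 0.10), Id2 (0.30 ± 0.08) and Klf13 (0.24 ± 0.07), were also named after their values were seen, and Id proteins are known as inhibitors of helix-loop-helix factors. Each of these rises was lost after median scaling and on leaving out single embryos (adjusted p values from 0.055 to 0.14). The embryos were any but Rb null embryo 2 for Id1 and any of the 6 for Klf13. For Id2 they were Rb null embryos 1 or 2 and wild type embryos 2 or 3. The Klf13 change was 0.02 with the mean of its probe sets (adjusted p = 0.89), and its call was also lost after quantile normalization (0.17, adjusted p = 0.15), with the replicate block (adjusted p = 0.065) and with the robust trend (adjusted p = 0.051).

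Of iron handling genes, 2 fell and 1 rose of 10, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.49, or adjusted p = 0.67 with an estimated correlation). Hmox1, the haem-degrading oxygenase, rose to 4048 ± 204 from 3143 ± 45.0 (0.36 ± 0.05), and the ferritin gene Fth1 fell by 0.25 ± 0.05, a call lost after cyclic loess (-0.04, adjusted p = 0.42) and quantile normalization (-0.09, adjusted p = 0.14). Leaving out Rb null embryo 1 (adjusted p = 0.064), wild type embryo 2 (adjusted p = 0.055) or wild type embryo 3 (adjusted p = 0.062) also ended the Fth1 call. Slc11a2, an iron transporter gene, fell by 0.35 ± 0.10, but its call was lost on leaving out any embryo except Rb null embryo 3, with adjusted p values from 0.075 to 0.13, and after quantile normalization (adjusted p = 0.056).

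DNA replication and mitosis genes were lower in Rb null livers by small amounts. Of 44 tested genes of the replication list, 10 fell, or 12 adjusted over the list alone, and the other members did not pass (median -0.15, camera adjusted p = 4.9e-06, or adjusted p = 0.024 with an estimated correlation). Of 37 mitosis genes 10 fell, the same count adjusted over the list alone (median -0.11, camera adjusted p = 2.2e-04, or adjusted p = 0.038 with an estimated correlation). The replication median lay below the 95% range of random lists matched on signal (-0.11 to 0.05), whereas the mitosis median lay within it (-0.12 to 0.06). Rrm2, the small subunit of ribonucleotide reductase, fell from 2828 ± 67.0 to 2178 ± 65.3 (-0.37 ± 0.05, adjusted p = 0.0023). Mcm5, a subunit of the replicative helicase, fell from 4431 ± 257 to 3502 ± 120.5 (-0.33 ± 0.06), and the DNA ligase gene Lig1 fell by 0.35 ± 0.06. Mybl2, a transcription factor of cycling cells, fell by 0.41 ± 0.09, a call lost without Rb null embryo 2 (adjusted p = 0.055), wild type embryo 1 (adjusted p = 0.052) or wild type embryo 3 (adjusted p = 0.055) and with the mean of its probe sets (-0.14, adjusted p = 0.42). Among mitosis genes, Birc5, which encodes survivin, fell by 0.32 ± 0.06, the kinase gene Aurka by 0.30 ± 0.05 and the checkpoint gene Mad2l1 by 0.28 ± 0.07. The Mad2l1 call was lost after quantile normalization (adjusted p = 0.058) and without Rb null embryo 1 (adjusted p = 0.053) or wild type embryo 3 (adjusted p = 0.068). Ccna2, the cyclin of S phase and mitotic entry, fell from 3739 ± 371 to 2694 ± 319 (-0.47 ± 0.10), a call lost without Rb null embryo 2 (adjusted p = 0.0504).

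Inhibitors of cyclin-dependent kinases and p53 targets showed no common direction. Of 14 tested, 2 rose and 1 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.95, also with an estimated correlation). Plk2, a p53-inducible kinase, rose from 361 ± 34.4 to 683 ± 49.8 (0.83 ± 0.09), and the inhibitor gene Cdkn1c rose by 0.25 ± 0.05, a call lost after median scaling (adjusted p = 0.057). Gadd45a, induced by DNA damage, fell from 1895 ± 35.2 to 1401 ± 127 (-0.43 ± 0.07). In this list the median (-0.01) and the mean (0.05) differed in sign, and camera gave a downward direction. Of 22 genes of the apoptosis machinery 5 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.95, also with an estimated correlation). Bnip3 had the largest rise, and Bcl2l1, the anti-apoptotic Bcl-x gene, fell from 2140.0 ± 158 to 1378 ± 146 (-0.62 ± 0.09), and the adaptor gene Tradd fell by 0.53 ± 0.09. Bcl2l2, another gene against apoptosis, rose by 0.47 ± 0.13, but the call was lost on leaving out any embryo except wild type embryo 1, with adjusted p values from 0.076 to 0.093, and after quantile normalization (adjusted p = 0.078). The apoptosis list had a median of 0.01 and a mean of 0.06 while camera gave a downward direction, and its median was -0.07 after quantile or cyclic loess normalization and -0.06 after median scaling.

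Hypoxia and glycolysis genes had the highest median of the 23 lists that could be tested. Of 30 tested members 22 rose, 1 fell and 7 did not pass, or 23 and 1 adjusted over the list alone (median 0.58, camera adjusted p = 1.0e-12, or adjusted p = 0.023 with an estimated correlation). Beside Ddit4, Bhlhe40 and Bnip3, Pfkp, an isoform of phosphofructokinase, rose from a wild type signal below the filter (84.2 ± 4.56) to 250.1 ± 28.9 (1.16 ± 0.12, adjusted p = 6.0e-04). Genes named after their values were seen were Hk2, a hexokinase, which rose from 621 ± 84.2 to 1393 ± 63.6 (1.11 ± 0.10), P4ha1, a collagen prolyl hydroxylase (1.08 ± 0.08), Vegfa, the growth factor of vessels (1.03 ± 0.15), and Pgk1, a glycolytic kinase, which rose from 4139 ± 202 to 6100.0 ± 65.7 (0.56 ± 0.05). The member that fell, also named after its value was seen, was Slc2a1, a glucose transporter abundant in erythroid cells (-0.39 ± 0.10, adjusted p = 0.026). That call was lost after cyclic loess normalization (-0.30, adjusted p = 0.056) and without Rb null embryo 2, Rb null embryo 3, wild type embryo 1 or wild type embryo 3 (adjusted p values from 0.051 to 0.080). Hif1a, whose protein is mainly controlled after translation, was at -0.00 ± 0.05 and the lactate dehydrogenase gene Ldha at 0.14 ± 0.09, and neither passed the test. Both were likewise named after their values were seen, and Ldha passed after quantile normalization (0.31, adjusted p = 0.011) and cyclic loess (0.33, adjusted p = 0.0095). The 3 prime to 5 prime signal ratio, a measure of RNA integrity on these arrays, was 0.859 ± 0.0296 in Rb null and 0.919 ± 0.00430 in wild type for Gapdh (exact permutation p = 0.1), and 1.25 ± 0.0616 and 1.16 ± 0.0441 for Actb (exact permutation p = 0.2).

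**Figure D2:**
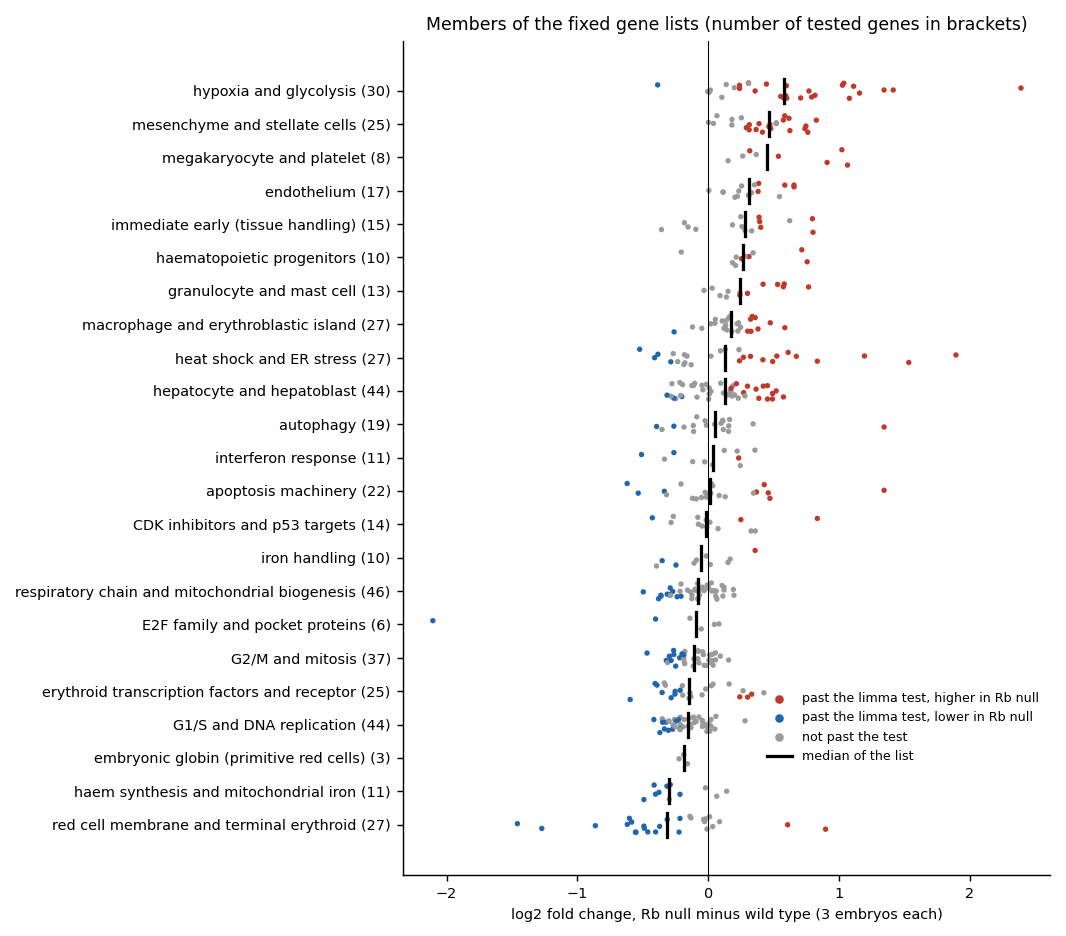
Log2 fold change of each tested member of 23 gene lists (horizontal axis, Rb null minus wild type, n = 3 embryos per genotype), coloured by the limma test, with list medians as black bars. Medians run from -0.31 for red cell membrane and terminal erythroid genes to 0.58 for hypoxia and glycolysis genes, and the embryonic globin, apoptosis, interferon and autophagy medians change sign under another scaling.

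Heat shock and endoplasmic reticulum stress genes split. Of 27 tested, 12 rose and 4 fell, or 12 and 7 adjusted over the list alone, and camera did not pass (median 0.13, adjusted p = 0.17, or adjusted p = 0.25 with an estimated correlation). The median lay above the 95% range of random lists matched on signal (-0.13 to 0.07), and after quantile normalization the camera adjusted p was 0.0099. After median scaling the median was 0.05 (adjusted p = 0.084). Hspa1a rose from 62.4 ± 22.5 to 363 ± 26.8 (1.89 ± 0.16), Hspa1b rose from 104 ± 14.3 to 395 ± 19.7 (1.53 ± 0.11), Trib3, a pseudokinase of the integrated stress response, rose 2.29-fold from 173 ± 22.1 to 459 ± 4.92, and Atf3, a stress-induced transcription factor, rose 1.78-fold (0.83 ± 0.10). The members that fell, named after their values were seen, were Hsph1 (-0.52 ± 0.06), Eif2ak1, the haem-regulated kinase of translation initiation (-0.41 ± 0.06), Dnaja1 (-0.38 ± 0.06) and Hspa8 (-0.29 ± 0.07). The Hspa8 call was lost after quantile normalization (-0.12, adjusted p = 0.38) and without Rb null embryo 1, wild type embryo 1 or wild type embryo 2 (adjusted p values from 0.052 to 0.071). Of 15 immediate early genes, a list fixed to follow tissue handling, 5 rose, or 6 adjusted over the list alone (median 0.28, camera adjusted p = 0.020, or adjusted p = 0.098 with an estimated correlation). Ier3 rose by 0.80 ± 0.09, Btg1 by 0.80 ± 0.11, Ier2 by 0.40 ± 0.07 and Nfkbia by 0.39 ± 0.08. Its camera call was also lost with the stricter signal filter (adjusted p = 0.52) and without probe sets that can bind several transcripts (adjusted p = 0.051).

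Autophagy and interferon response genes had medians near 0. Of 19 autophagy genes 1 rose (Bnip3) and 2 fell, Gabarapl2 (-0.39 ± 0.08) and Becn1 (-0.26 ± 0.06), with the same counts adjusted over the list alone (camera adjusted p = 0.94, also with an estimated correlation). Of 11 interferon response genes 1 rose, H2-K1 (0.23 ± 0.06), and 2 fell, Igtp (-0.51 ± 0.13) and Psmb10 (-0.26 ± 0.08), or 2 and 3 adjusted over the list alone (camera adjusted p = 0.92, or adjusted p = 0.94 with an estimated correlation). Calls were lost on leaving out single embryos (adjusted p values from 0.051 to 0.14). The embryos were Rb null embryos 1 or 3 and wild type embryos 2 or 3 for Becn1. For H2-K1 they were Rb null embryos 1 or 2 and wild type embryos 1 or 3. For Igtp they were Rb null embryo 2 and wild type embryos 1 or 3, and for Psmb10 any of the 6. The H2-K1 call was also lost without probe sets that can bind several transcripts (0.40, adjusted p = 0.14) and after median scaling (0.16, adjusted p = 0.10). Camera gave a downward direction for autophagy, whose median (0.05) and mean (0.06) were above 0, and for interferon response, whose median was 0.03 and whose mean was below 0, and quantile normalization turned both medians below 0.

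Respiratory chain genes were lower by small amounts. Of 46 tested, 11 fell, the same count adjusted over the list alone (median -0.08, camera adjusted p = 7.8e-04, or adjusted p = 0.038 with an estimated correlation). Ndufa5 fell from 3705 ± 193 to 2611 ± 100.2 (-0.50 ± 0.06, adjusted p = 0.0011) and Ndufc1 fell by 0.38 ± 0.05, both encoding subunits of respiratory complex I. Cox6a1 fell by 0.36 ± 0.06 and Ndufb7 by 0.36 ± 0.08, the latter call being lost after cyclic loess (adjusted p = 0.053) and without wild type embryo 2 (adjusted p = 0.054) or wild type embryo 3 (adjusted p = 0.058). Camera no longer passed after quantile normalization (median -0.03, adjusted p = 0.38). Random lists matched on signal had a median of -0.08 (95% range from -0.15 to -0.02), so the list's median was no lower than that of equally bright genes.

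Many markers of other cell types of the fetal liver were higher in Rb null livers. Of 25 mesenchyme and stellate cell genes 18 rose, or 20 adjusted over the list alone (median 0.46, camera adjusted p = 1.6e-09, or adjusted p = 0.023 with an estimated correlation). Collagen genes were among them, with Col6a1 (0.83 ± 0.12) and Col3a1 (from 921 ± 91.5 to 1592 ± 13.8, 0.76 ± 0.07), beside Mdk, the growth factor midkine (0.75 ± 0.10), and Fbln2, a fibulin (0.74 ± 0.06). Of 17 endothelial genes 6 rose, or 11 adjusted over the list alone (median 0.31, camera adjusted p = 1.5e-04, or adjusted p = 0.038 with an estimated correlation), including Kdr, a receptor of vascular endothelial growth factor (0.66 ± 0.08), the transcription factor gene Sox18 (0.66 ± 0.08), Emcn, which encodes endomucin (0.59 ± 0.13, from a wild type mean of 136 that lay below the signal filter), and Sox17 (0.39 ± 0.10). The Sox17 call was lost after quantile normalization (adjusted p = 0.0995) and on leaving out any embryo except wild type embryo 3 (adjusted p values from 0.063 to 0.084).

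Among blood lineages, 5 of 8 megakaryocyte and platelet genes rose, or 6 adjusted over the list alone (median 0.45, camera adjusted p = 9.2e-05, or adjusted p = 0.076 with an estimated correlation). The platelet glycoprotein genes Gp5 and Gp1bb rose from 150.8 ± 22.0 to 370 ± 34.0 (1.07 ± 0.12) and from 279 ± 43.0 to 614 ± 32.7 (1.02 ± 0.11), and Vwf, the von Willebrand factor gene, rose 1.88-fold (0.91 ± 0.07), and Mylk, a myosin kinase gene, rose 1.45-fold (0.54 ± 0.09). RNA came from whole livers, so the cells that made Vwf and Mylk were not identified. The endothelium and mesenchyme lists rose in the same livers. Of 13 granulocyte and mast cell genes 7 rose, the same count adjusted over the list alone (median 0.24, camera adjusted p = 7.8e-04, or adjusted p = 0.049 with an estimated correlation), among them the lactoferrin gene Ltf (0.77 ± 0.12), S100a8, from 2140.3 ± 24.2 to 3213 ± 27.7 (0.57 ± 0.05), and the eosinophil granule genes Prg2 (0.58 ± 0.09) and Epx (0.53 ± 0.13). The Epx call was lost after quantile normalization (adjusted p = 0.056) and without Rb null embryos 1 or 2 or wild type embryos 1 or 2 (adjusted p values from 0.064 to 0.087). Of 10 progenitor genes 4 rose, or 6 with 1 lower adjusted over the list alone (median 0.27, camera adjusted p = 0.0060, or adjusted p = 0.076 with an estimated correlation). Kit, the receptor of stem cell factor, rose from 501 ± 76.9 to 875 ± 27.0 (0.76 ± 0.11, adjusted p = 0.0024), and Ikzf1, the Ikaros transcription factor gene, rose from 332 ± 6.08 to 577 ± 27.1 (0.72 ± 0.08). Prom1 (0.31 ± 0.07) and Myb (0.26 ± 0.07) also rose, but the Prom1 call was lost after quantile normalization (adjusted p = 0.065) and without Rb null embryo 2, wild type embryo 1 or wild type embryo 3 (adjusted p values from 0.055 to 0.065). The Myb call was lost after median scaling (adjusted p = 0.098) and on leaving out any embryo except Rb null embryo 1 (adjusted p values from 0.052 to 0.086).

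Of 27 macrophage and erythroblastic island genes 8 rose and 1 fell, with the same counts adjusted over the list alone (median 0.17, camera adjusted p = 0.0027, or adjusted p = 0.19 with an estimated correlation). Lyz2, a lysozyme gene, rose by 0.48 ± 0.10, Itgav, an integrin gene, by 0.38 ± 0.06, the tetraspanin gene Cd53 by 0.59 ± 0.14 and the lysosomal gene Laptm5 by 0.36 ± 0.07, while the cathepsin gene Ctsb, named after its value was seen, fell by 0.26 ± 0.08. Ctsb was no longer called after quantile normalization (-0.12, adjusted p = 0.27) or without Rb null embryo 1, Rb null embryo 2, wild type embryo 1 or wild type embryo 3 (adjusted p values from 0.099 to 0.14). The Cd53 call was lost without Rb null embryo 2, Rb null embryo 3 or wild type embryo 1 (adjusted p values from 0.054 to 0.059), and the Itgav call with the mean of its probe sets (adjusted p = 0.47). The lymphoid genes past the signal filter, Cd79a (0.04 ± 0.13) and Rag1 (-0.12 ± 0.12), did not pass the test.

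Hepatocyte and hepatoblast genes moved in both directions. Of 44 tested, 13 rose and 3 fell, or 14 and 5 adjusted over the list alone, and camera did not pass (median 0.13, adjusted p = 0.11, or adjusted p = 0.16 with an estimated correlation), although it did after quantile normalization (adjusted p = 5.9e-04). After median scaling the median was 0.06 (adjusted p = 0.16). As deposited it lay above the 95% range of random lists matched on signal (-0.12 to 0.03). The clotting factor genes F5 (0.58 ± 0.07) and F2 (from 1098 ± 74.2 to 1594 ± 16.1, 0.52 ± 0.06) and the hepatic transcription factor genes Hnf4a (0.49 ± 0.11) and Foxa3 (0.49 ± 0.09) rose. The members that fell, named after their values were seen, were the plasma protein genes Apoa1 (-0.31 ± 0.07) and Alb (-0.20 ± 0.05) and the urea cycle gene Otc (-0.26 ± 0.08). Alb read 13754 ± 258 against 15834 ± 825 as deposited, but its direction reversed after quantile (0.04, adjusted p = 0.52) and cyclic loess normalization (0.04, adjusted p = 0.55). The Apoa1 change shrank to -0.11 after cyclic loess and was no longer called (adjusted p = 0.087). The calls of these genes were also lost on leaving out single embryos (adjusted p values from 0.058 to 0.13). The embryos were any but wild type embryo 1 for Alb and any but wild type embryo 2 for Otc. For Apoa1 they were Rb null embryo 1, Rb null embryo 2 or wild type embryo 3. Some lists shared members, such as Bnip3 in 3 of them.

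**Figure D3:**
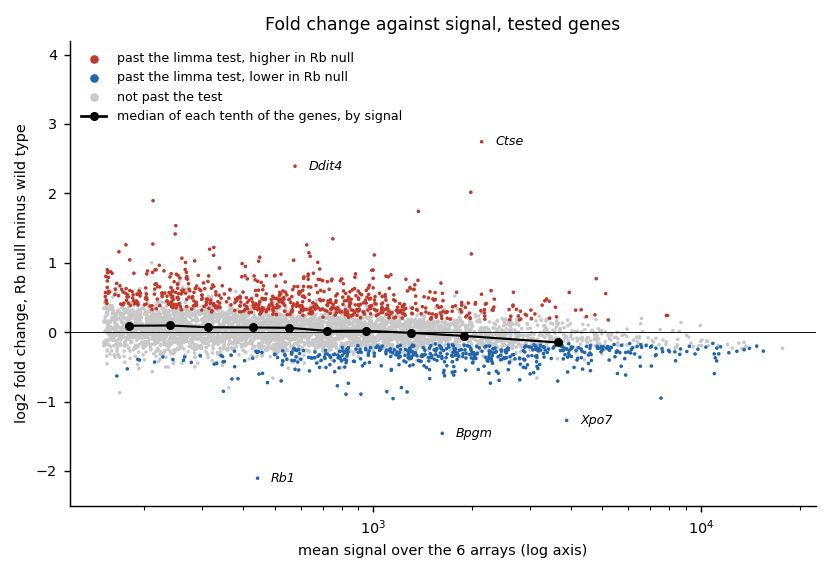
Log2 fold change of each tested gene (vertical axis, Rb null minus wild type) against its mean signal over the 6 arrays on a log axis, coloured by the limma test, with the medians of 10 equal groups of genes by signal joined as a black line. The medians run from 0.09 for the dimmest to -0.15 for the brightest group, and 177 of the 501 lower genes lie in the brightest group.

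The labels give no sex of the embryos. Xist, the RNA of the inactive X chromosome, read between 559.8 and 643 in Rb null and between 384 and 473 in wild type livers (0.48 ± 0.10, adjusted p = 0.011). Eif2s3y, a Y-linked gene, read between 186 and 211 and between 235 and 305 (-0.32 ± 0.12, adjusted p = 0.091, or adjusted p = 0.036 after quantile normalization), and Uty and Kdm5d stayed below the signal filter. No embryo lacked signal on the Xist probe set, so the sex of single embryos could not be told from these values.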

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

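The difference in the control probe sets below was found by a screen of all array controls, and its cause was not tested. Signal appeared in data that no gene comparison of the report used, namely the array's control probe sets for the transferrin receptor, which were higher in all 3 Rb null than in all 3 wild type livers. The 5 prime control read 385 ± 7.95 against 183 ± 13.02 (log2 fold change 0.91 ± 0.09, limma adjusted p over the controls 1.7e-04), the middle control 358 ± 3.81 against 241 ± 31.8 (0.50 ± 0.10, 0.0056) and the 3 prime control 2032 ± 62.7 against 1502 ± 143 (0.43 ± 0.08, 0.0024). The brightest regular probe set of Tfrc did not pass the test (0.02 ± 0.07, adjusted p = 0.89), whereas Tfrc passed without shared-probe suffixes (0.37, adjusted p = 0.032). The 3 prime to 5 prime ratio of these controls lay between 5.11 and 5.38 in Rb null and between 7.93 and 8.47 in wild type arrays. Of the other control probe sets, 4 were lower in Rb null arrays past the same threshold, those for pyruvate carboxylase 3 prime (-0.45 ± 0.07), the B1 repeat (-0.30 ± 0.05), the B2 repeat (-0.23 ± 0.06) and actin 5 prime (-0.21 ± 0.06).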

How the results depend on the processing

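Cyclic loess normalization, the E2F list without Rb1 and the terminal erythroid list without Xpo7 and Dmtn were chosen after the results had been seen, and the other alternatives were planned. Over the alternatives in which they were tested, the 107 genes named by the rule gave 1758 values with the same direction and side of the threshold. Another 111 values no longer passed and 11 newly passed. Some of these genes were not tested with the stricter filter or without shared-probe suffixes and gave no value there. The 33 genes named outside the rule gave 501, 81 and 3, and 2 values of Alb that reversed (0.04 after quantile normalization and 0.04 after cyclic loess). The count of higher genes was 428 with the stricter filter, 27 with a 2-fold minimum and between 419 and 553 when single embryos were left out. That of lower genes was 836 after median scaling, 3 with a 2-fold minimum and between 256 and 429 when single embryos were left out. Fewer genes were tested with the stricter filter and fewer arrays were fitted when an embryo was left out. With the replicate block, 639 genes were higher and 488 lower, and 1035 of these 1127 were shared with the 1191 reported, and replicates with the same number did not resemble each other (1 of 3 pairs had r above 0.1). The E2F list no longer passed camera without a filter (adjusted p = 0.093), with the stricter filter (0.503), with the replicate block (0.068), without shared-probe suffixes (0.176), with an estimated correlation (0.146) or without Rb1 (0.362), and it lay between 0.031 and 0.061 when single embryos were left out. An estimated correlation ended the calls of erythroid transcription factors, progenitors and megakaryocytes (0.0758 each), macrophages (0.185) and immediate early genes (0.0981). The stricter filter ended those of erythroid transcription factors (0.0577), progenitors (0.0923) and immediate early genes (0.516), the last also lost without shared-probe suffixes (0.0512). Respiratory chain genes did not pass after quantile normalization (0.376) or cyclic loess (0.378). Newly past camera were embryonic globins without a filter (0.0411, and between 0.0163 and 0.125 when single embryos were left out), and, after quantile normalization and cyclic loess, hepatocyte genes (5.9e-04 and 4.2e-04) and heat shock genes (0.0099 and 0.0095). Both lists also passed fry (3.7e-04 each), which makes no comparison with other genes. The apoptosis list, downward in camera, was upward in fry (0.0064). For these changed results the cause was not tested. The lists of replication, mitosis, haem synthesis, terminal erythroid, granulocyte, endothelium, mesenchyme and hypoxia genes passed under each of these alternatives. Signal over background and the number of arrays limit what small changes could be called.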

Other observations

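The 3 counts over other splits of the arrays were planned, and the other tests of this part were chosen after the results had been seen. Of the 10 splits of the 6 arrays into 3 and 3, only the real one, 1 split, called as many genes or lists as reported. It gave 690 higher and 501 lower genes and 15 lists, against at most 0 genes by limma and 9 lists in the others. At the preset correlation camera thus called lists even in splits without a called gene. With an estimated correlation it called 9 lists in the real split and 0 in the others. The other splits had between 66 and 295 genes at an unadjusted p below 0.05, where the real split had 1923. With 10 splits the share cannot fall below 0.1. Each other split put embryos of both genotypes into both groups, which adds the genotype difference to the spread within groups. Few gene calls were therefore likely in them in advance, and their counts do not measure what chance alone would give.

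Red cell genes were lower while markers of several other cell types were higher. A trend with signal between arrays is argued against as the whole cause, since after cyclic loess normalization the terminal erythroid list had an adjusted p = 2.8e-06 (median -0.31 before, -0.16 after) and haem synthesis an adjusted p = 9.4e-04 (-0.30 and -0.25). For the respiratory chain the call ended (adjusted p = 0.378, median -0.08 and -0.02) and random lists matched on signal had a median of -0.08, so the trend may account for that list. The 27 terminal members changed by unequal amounts (Cochran Q = 983, weighted mean -0.40). This spread cannot decide for or against a single lower share of erythroid cells. Other cells also make members such as Aqp1, and changes of dim members are understated, so unequal changes were likely either way. Mesenchyme and hepatocyte medians differed by 0.34 (permutation over genes, p = 8.0e-05), and after cyclic loess normalization they were 0.41 and 0.13. Genes of a list do not vary independently, so this p does not measure the spread between embryos. Random lists matched on signal also differed, with medians of 0.01 for mesenchyme and -0.04 for hepatocytes. The difference therefore cannot decide for or against an equal rise of all other cell types. A change of erythroid maturation, or of mesenchyme itself, beside a shift in cell shares stays open and was not tested.

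Hypoxia and glycolysis genes were higher, and after cyclic loess normalization the list still passed (adjusted p = 3.6e-18, median 0.58 before and 0.63 after). More degraded RNA would raise the 3 prime to 5 prime ratios. In Rb null arrays that of Gapdh was lower (0.859 against 0.919, or -2.84 pooled SD), which argues against it. That of Actb was higher (1.25 against 1.16, or 1.61 pooled SD), which keeps it open. Both gaps were small beside the ratios themselves, and the pooled SD rest on few arrays. The ratio of the transferrin receptor controls was also lower (5.27 ± 0.143 against 8.22 ± 0.274). These controls were picked after their own signals had been seen to differ between genotypes, so their ratio is no independent measure of RNA integrity. Handling or delay before lysis may also contribute and cannot be told apart from genotype here, as the immediate early list had an adjusted p = 0.0201 at the preset and 0.0981 with an estimated correlation. A response of the Rb null livers to low oxygen stays open and was not tested.

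DNA replication and mitosis genes were lower although the mutated gene restrains the cell cycle. A trend with signal as the whole cause is argued against for replication, which passed after cyclic loess normalization (adjusted p = 4.2e-04, median -0.15 before and -0.11 after) and lay below the 95% range of random lists matched on signal. It stays open for mitosis, which also passed (adjusted p = 0.0104, median -0.11 and -0.08) but lay within that range. A lower share of dividing erythroblasts could underlie these falls and stays open. Replication genes fell by less than haem synthesis genes (medians -0.15 and -0.30, a difference of 0.15, permutation over genes, p = 0.0896). Only a larger fall of replication genes was set to count against that share, so this p cannot decide it. A change of the cell cycle within cells was not tested.

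Among the 20 tested genes nearest Rb1 on its chromosome 5 were changed, against 22.6% of genes elsewhere (one-sided Fisher exact p = 0.483, odds ratio 1.14). These were Xpo7 (-1.27), Rgcc (-0.74), Dmtn (-0.58), Fndc3a (0.46) and Lcp1 (0.39), and the Fndc3a call was lost without Rb null embryo 1 (adjusted p = 0.051) or Rb null embryo 2 (adjusted p = 0.054). Without Xpo7 and Dmtn the terminal erythroid list had a median of -0.22 (camera adjusted p = 3.4e-06).

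The 10 gene families below were taken by symbol after members such as Mrps25, Col6a1 and Mt1 had been seen to change, so their p values describe what prompted them and are no independent evidence. Proteasome subunits were lower in 19 of 34 genes (median -0.21, camera adjusted p = 2.5e-09, or adjusted p = 0.019 with an estimated correlation), among them Psmd13 (-0.39 ± 0.07) and Psmd4 (-0.39 ± 0.05). Mitochondrial ribosomal proteins were lower in 14 of 57 (median -0.18, adjusted p = 1.2e-07, or adjusted p = 0.044 with an estimated correlation), among them Mrpl20 (-0.47 ± 0.07). Collagen chains were higher in 12 of 18 (median 0.35, adjusted p = 2.1e-06, or adjusted p = 0.044 with an estimated correlation), among them Col6a2 (1.09 ± 0.09) and Col5a2 (0.80 ± 0.06). These families kept their direction after cyclic loess normalization, whereas the median of cytosolic ribosomal proteins moved from -0.14 to 0.02, and their camera adjusted p = 0.0017 as deposited became adjusted p = 0.23 with an estimated correlation. Of 3 metallothionein genes 2 fell, Mt1 (-0.95 ± 0.06) and Mt2 (-0.60 ± 0.06). Their median was -0.60, or -0.39 after cyclic loess normalization (camera adjusted p = 0.0058 as deposited, or adjusted p = 0.095 with an estimated correlation). Genes with an Eif symbol, which include kinases and binding proteins beside translation factors (median -0.14), transfer RNA synthetases (-0.13), chaperonin subunits (-0.17) and splicing proteins (-0.15) passed camera at the preset correlation but not with an estimated correlation (adjusted p values from 0.052 to 0.066). After cyclic loess normalization the medians were -0.08 for Eif genes, -0.13 for synthetases, -0.09 for chaperonins and -0.08 for splicing proteins, and camera no longer passed for chaperonins (adjusted p = 0.12) or cytosolic ribosomal proteins (adjusted p = 0.16). Ubiquitin-conjugating enzymes (-0.04) did not pass as deposited (adjusted p = 0.12).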
